A study of Physcomitrium patens with 8 samples.

How the data were processed

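Total RNA from protonemata (the filamentous juvenile stage) of the moss Physcomitrium patens was measured on 8 two-colour Agilent arrays. Per the labels, tissue was 10 days old and was held for 30 min at 25, 34 or 38 °C. The 4 sample groups, with 2 biological replicates each, were wild type at 34 °C (WT34), wild type at 38 °C (WT38), the CNGCb knockout at 25 °C (CNGCb25) and the CNGCb knockout at 34 °C (CNGCb34). Per the labels, every array carried its sample in Cy5 and wild type held at 25 °C (WT25) in Cy3, so no dye swap was made.

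The deposited scanner files hold spot intensity, as mean signal and median local background per channel on a linear scale, with flags for outlier and saturated spots. Per the file headers, they were made with Agilent Feature Extraction, version 10.5.1.1 for all replicate 1 arrays and version 10.7.3.1 for all replicate 2 arrays. The 4 replicate 1 arrays lay on slide 1 and the 4 replicate 2 arrays on slide 2. The deposited files also give a log10 ratio of Cy5 to Cy3 per spot, from Feature Extraction's own background and dye correction, and this ratio was exactly 0 for 31.7 to 41.3% of spots. The deposited series table holds log2 ratios. Set against the scanner ratios, its columns had a slope of 1 in the direction Cy5 over Cy3 wherever the scanner ratio was not 0. Column medians of that table were 0 on the 4 slide 1 arrays, and 0.09, -0.053, -0.097 and -0.091 on the slide 2 arrays of WT34, WT38, CNGCb25 and CNGCb34. On slide 2 these medians equalled the value the table gives where the scanner ratio was 0. The step that put them there is not given in the sources used here.

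Each array carried 41384 spots outside the controls for 28178 gene models. Of these, 14972 models had 1 spot and 13206 had 2 spots of the same sequence, which were averaged. Probes Pp_158998 and Pp_65913 shared 1 sequence, so there were 28177 distinct sequences. Probes are given by the identifiers of the files. No probe had a description in the files, and 0 of the identifiers matched the RefSeq gene table used here (assembly ASM5946719v1, 27567 genes), so genes are not named and no genome coordinates are given. The 26 gene lists fixed before the data were examined were text matches on gene descriptions. All 26 matched nothing and are void: small HSP, HSP70, HSP90, HSP100/Clp, DnaJ, chaperonin, cochaperones, heat shock factors, CNGC family, calcium signalling, ER folding, ROS enzymes, LEA and ABA, AP2/ERF and DREB, WRKY MYB NAC, light harvesting and photosystem, early light-induced, cytosolic ribosomal, proteasome and ubiquitin, cell wall, cell cycle and histone, oxylipin and phenylpropanoid, sugar osmolytes, caulonema and rhizoid markers, bud and gametophore markers, and chloroplast-encoded transcripts. For the same reason the knocked-out gene was not checked in the arrays labelled CNGCb.

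Background was corrected by normexp with an offset of 50, log2 ratios were normalised within each array by loess, and control and outlier-flagged spots had no weight (limma 3.58.1 in R 4.3.3). One linear model over all 8 arrays gave each group's mean log2 ratio, with moderated errors and Benjamini-Hochberg adjustment at 0.05 over the gene models of each comparison. It had 4 residual degrees of freedom and a prior of 2.49. Log2 ratios of the 4 groups were tested against 0. Such a test leaves out the spread of the WT25 control itself, and an effect of the dyes on a probe cannot be separated from a difference in RNA. Dye effects that are constant cancel in differences between groups. The design fixed before the data were examined named, without gene descriptions, at most 2 probes that rose and 2 that fell per comparison, the largest changes past the threshold with the same sign in both replicates and well above background in both arrays on the brighter side.

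Because slide equals replicate number and each slide holds all 4 groups, slide was also fitted as a block. The other alternatives were no background correction, an offset of 10, median centring, the deposited ratios, a filter on dim probes, outlier spots kept, a trended and robust prior, a fold threshold and each array left out in turn. Turned signs, a crossed block and a correction for GC content were added after the data were seen. On simulated arrays with the measured spread, the fit of CNGCb34 vs WT34 over 28178 models recovered 38% of models changed by 1 on the log2 scale and 84% of those changed by 2. For CNGCb34 vs CNGCb25 these shares were 40% and 80%. The simulation changed 50 models at each of 1, 2, 3 and 5 and drew all arrays as independent normal values. Data with fewer changed models, or with structure shared among arrays, may give lower shares, so these do not bound what 0 calls could miss. With 2 arrays per group, the number of arrays limits the precision.

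A further classification was made after the files were opened and before any ratio was compared between arrays. The peptide encoded on the complementary strand of each 60-base probe was compared with reference peptides and motifs of protein families. These references were written from general knowledge, not taken from a database, so a class is a sequence similarity and not a gene name. Identity thresholds of 45, 50, 55 and 65% were tried, and 55% over at least 15 residues was chosen from the number of matches in real and reversed sequences. In the same step 1 motif was widened, a single strand was kept, and the heat shock families were pooled because each alone was too small. The classes with at least 5 probes were heat shock protein-like (11 probes), calmodulin-like EF-hand (9), protein kinase (7) and tubulin (6), against 0 in reversed sequences for each. They were tested with camera and fry.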

Results

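The transcript response of Physcomitrium patens protonemata to 30 min of heat was measured in wild type and in a knockout of CNGCb, a member of the cyclic nucleotide-gated channel family of plant cation channels. The series compared wild type at 34 and 38 °C and the knockout at 25 and 34 °C, each on 2 arrays, with wild type at 25 °C as the reference on every array. Between 28.4 and 48.9% of the 28178 gene models were well above background in the Cy5 sample channel, the lowest share on WT34 replicate 1 and the highest on CNGCb25 replicate 2. No spot was saturated. Replicates are separate biological samples per the labels. Across gene models, which are not independent replicates, the log2 ratios of the replicate pair correlated at r = 0.41 in WT34, 0.41 in WT38 and 0.56 in CNGCb34, but at -0.40 in CNGCb25. In all groups, each array correlated more closely with some array of another group than with its own replicate. WT34 replicate 1 reached 0.78 and WT38 replicate 2 reached 0.77 with CNGCb34 replicate 1, and WT34 replicate 2 reached 0.63 with CNGCb34 replicate 2.

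**Figure D1:**
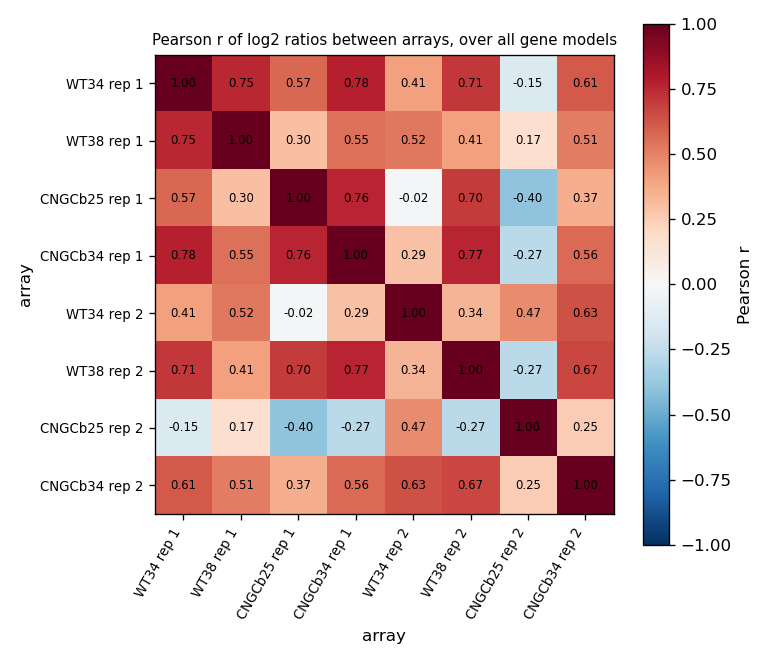
Pearson correlation of log2 ratios (Cy5 sample over Cy3 reference) between each pair of the 8 arrays, over all gene models; rows and columns are arrays, and colour and number give r. The CNGCb25 pair is the lowest of all pairs at -0.40.

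The comparison of WT34 with WT25 asked which transcripts responded to 34 °C in wild type. The sequence shared by Pp_158998 and Pp_65913, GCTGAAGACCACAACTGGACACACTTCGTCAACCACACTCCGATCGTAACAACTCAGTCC, gave the largest rise. Pp_158998 was higher by 5.83 ± 0.04 on the log2 scale (SD, n = 2), or 56.8-fold, with a limma adjusted p of 0.00176, and Pp_65913 by 5.90 ± 0.11 (SD, n = 2). Since these probes are identical in sequence, they count as 1 observation made at separate spots. Pp_92407 (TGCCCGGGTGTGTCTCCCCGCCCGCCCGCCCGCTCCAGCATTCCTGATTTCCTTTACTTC) was lower at -1.04 ± 0.02 (SD, n = 2; limma adjusted p = 0.0357), and was also low in unheated CNGCb25, at -1.08 and -0.76 on the replicate arrays. Pp_155751 (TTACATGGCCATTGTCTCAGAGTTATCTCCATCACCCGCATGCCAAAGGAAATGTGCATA) was lower at -0.85 ± 0.13 (SD, n = 2; limma adjusted p = 0.0424) and lay at 0.08 and -0.05 in CNGCb25. Of 15 alternative settings, the call was lost in 8 for Pp_92407 and 12 for Pp_155751. In all, 40 gene models passed, 33 higher and 7 lower. The 33 had a median log2 ratio of 1.46, and 27 of them changed at least as much as 1 on the log2 scale. With slide as a block 1786 passed, 942 higher and 844 lower, including all 40. The count fell to between 2 and 32 when 1 array was left out.

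At 38 °C the wild type showed the same leading sequence. Pp_158998 was higher by 5.81 ± 0.27 (SD, n = 2; limma adjusted p = 0.00164) and Pp_65913 by 5.82 ± 0.24 (SD, n = 2). Pp_231826 (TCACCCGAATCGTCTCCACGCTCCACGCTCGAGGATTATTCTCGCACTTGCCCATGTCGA) was lower at -1.41 ± 0.31 (SD, n = 2; limma adjusted p = 0.0447), and was similarly low in unheated CNGCb25, at -1.27 and -1.08. Pp_63693 (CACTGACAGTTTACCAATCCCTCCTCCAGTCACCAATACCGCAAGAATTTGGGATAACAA) was lower at -1.30 ± 0.05 (SD, n = 2; limma adjusted p = 0.0447), with 0.12 and 0.08 in CNGCb25. The call was lost in 11 of 15 alternative settings for Pp_231826 and 9 for Pp_63693. Of 59 gene models that passed, 41 were higher, with a median of 1.56, and 18 were lower, with a median of -0.78. With slide as a block 243 passed, 148 higher and 95 lower, including all 59. The count fell to between 1 and 38 when 1 array was left out. Of the 33 models higher at 34 °C, 24 were among the 41 higher at 38 °C, where independent lists would share 0.048. Both lists were set against the same reference RNA, so part of this overlap may come from it. They were also called with the same error per probe, so the value for independent lists is not a chance level.

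The group means that share the reference were also correlated with each other. WT34 and WT38 correlated at r = 0.84 across gene models, against -0.19 simulated for unchanged groups with the covariance of the replicate differences, and the covariance was 0.072 against -0.007. When the ratios came from different slides, r was 0.61. WT38 and CNGCb25 correlated at 0.62, against -0.52 simulated, with a covariance of 0.048 against -0.038, at 0.43 when the ratios came from different slides, and at 0.30 and -0.27 within slide 1 and slide 2. WT34 and CNGCb25 correlated at 0.50, below the simulated 0.68, with a covariance of 0.034 against 0.045, and at -0.08 when the ratios came from different slides. With CNGCb25 replicate 1 turned in sign, CNGCb25 correlated with WT34 at -0.25 and with WT38 at -0.52, and with replicate 2 turned at 0.25 and 0.52. A dye or reference effect common to both replicates cancels in the replicate differences. The simulated values leave such an effect out, so a correlation above them does not exclude it. The simulated values with WT38 were negative because its replicate differences ran against those of the other groups. They also take replicate numbers as pairing whatever the arrays share. If the WT38 numbers were crossed, the simulated values with WT38 would change sign. The excess of the WT38 correlations over them therefore depends on that pairing, and no conclusion is drawn from it.

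The comparison of the unheated knockout with unheated wild type asked for effects of genotype without heat. One gene model passed, Pp_233161 (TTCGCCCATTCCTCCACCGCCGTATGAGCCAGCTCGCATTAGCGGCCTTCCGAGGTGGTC), at -1.37 ± 0.10 (SD, n = 2; limma adjusted p = 0.0422). In CNGCb34 it lay at -1.28 ± 0.13 (SD, n = 2), and in WT34 and WT38 its means were -0.58 and -0.65. With slide as a block 0 models passed, and the adjusted p of Pp_233161 was 0.0801. An unadjusted p under 0.05 was found for 3726 models. Because the CNGCb25 replicates correlated at -0.40 over all gene models, although the labels give the same dyes for both, the direction of CNGCb25 ratios is not settled. With the sign of either replicate turned, 0 models passed.

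The knockout at 34 °C was also compared with unheated wild type. Pp_158998 was higher by 6.07 ± 0.28 (SD, n = 2; limma adjusted p = 0.00123) and Pp_65913 by 6.07 ± 0.20 (SD, n = 2). Pp_92153 (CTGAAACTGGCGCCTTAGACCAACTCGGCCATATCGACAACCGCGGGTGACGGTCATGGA) was lower at -1.39 ± 0.42 (SD, n = 2; limma adjusted p = 0.028), with 0.05 and 0.34 in CNGCb25. Pp_75717 (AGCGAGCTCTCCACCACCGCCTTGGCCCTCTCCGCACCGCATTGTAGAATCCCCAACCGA) was lower at -1.29 ± 0.21 (SD, n = 2; limma adjusted p = 0.0296), and at -1.53 and -0.92 in unheated CNGCb25. In WT34 and WT38 Pp_92153 lay at -1.12 and -1.28 (limma adjusted p = 0.06 and 0.0577), a similar decrease in heated wild type that fell short of the threshold. The call was lost in 8 of 15 alternative settings for Pp_92153 and 9 for Pp_75717. Of 180 models that passed, 128 were higher and 52 lower. With slide as a block 1000 passed, 577 higher and 423 lower, including all 180. The count fell to 2 without CNGCb34 replicate 2. A list of another length than that of WT34 does not show a difference between genotypes, which was tested directly in CNGCb34 vs WT34.

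**Figure D2:**
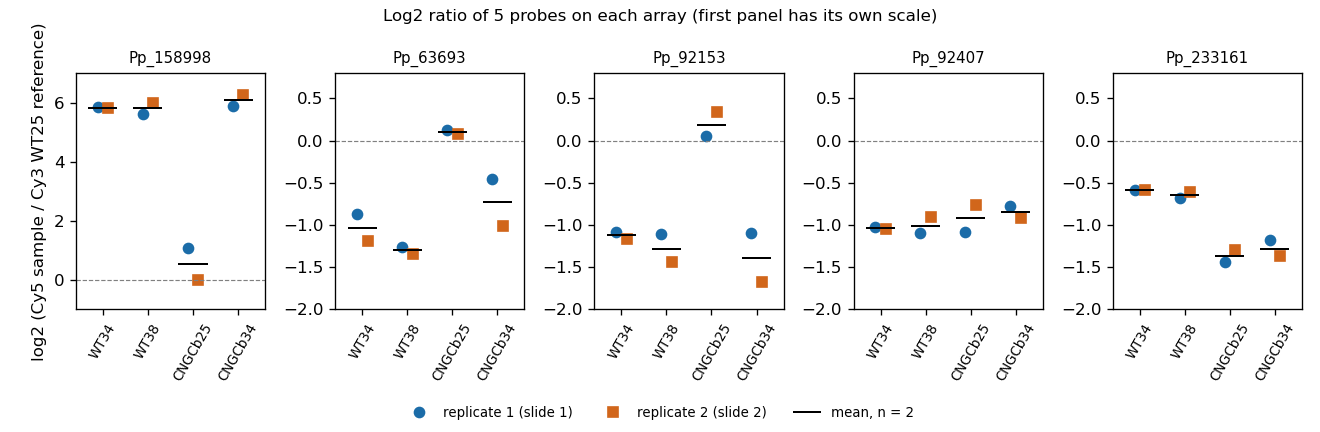
Log2 ratio of Cy5 sample over Cy3 WT25 reference for 5 named probes on each array, with circles for replicate 1, squares for replicate 2 and lines for the mean of 2. Pp_158998 lies between 5.62 and 6.27 in all heated arrays and at 1.07 and -0.02 in CNGCb25, whereas Pp_92407 is low in every group.

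The response of the knockout itself to 34 °C was given by CNGCb34 against CNGCb25, in which a constant dye effect and the reference cancel. Pp_158998 was higher by 5.55 (limma adjusted p = 0.02), at 4.80 on slide 1 and 6.30 on slide 2, and Pp_65913 by 5.61 (limma adjusted p = 0.0271), at 4.79 and 6.42. In this comparison 6 gene models passed, all higher, and 0 were lower. All 6 were among the models higher in WT34 and in WT38, where independent lists would share 0.00703 and 0.00873. These lists also share the error per probe, so those values are not a chance level. With slide as a block 19 passed, all higher, including the 6. With the Feature Extraction ratios 4 passed, 1 higher and 3 lower. With CNGCb25 replicate 1 or replicate 2 turned in sign, 8 and 9 passed, all higher. A single call remained when either CNGCb34 array was left out.

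CNGCb34 was compared with WT34 to ask whether the genotypes differed after the same heat. No gene model passed in limma (0 of 28178), 499 had an unadjusted p under 0.05, and 0 passed with slide as a block. The Feature Extraction ratios gave 1 call. WT38 against WT34, the temperature step in wild type, also gave 0 in limma, with 259 at an unadjusted p under 0.05 and 0 with slide as a block. The test of whether the response to 34 °C differed between genotypes gave 0 in limma, 1096 at an unadjusted p under 0.05 and 0 with slide as a block or with either CNGCb25 replicate turned in sign. Its wild type response is the WT34 ratio against the reference, so a constant dye effect does not cancel in that test. With the Feature Extraction ratios that test gave 3 calls, all lower. The unadjusted counts of 499, 259 and 1096 were each below a share of 0.05 of the 28178 models. That share would be reached on average with no change at all, so these counts are no sign of differences. The tests may be conservative, for a reason not tested, and 0 calls does not show that the groups were alike. Pp_158998 differed little between the heated groups, with means of 5.83, 5.81 and 6.07 in WT34, WT38 and CNGCb34.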

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

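Turned signs, the crossed block and the GC correction were chosen after seeing the data. The calls in comparisons with WT25 depended on the processing, and the cause was not tested. With the replicate block, which is the slide, calls were 1786 for WT34, 243 for WT38, 0 for CNGCb25, 1000 for CNGCb34 and 19 for CNGCb34 vs CNGCb25, and the block changed no call in CNGCb34 vs WT34, WT38 vs WT34 or the heat by genotype test. The replicate numbers did not pair the samples throughout. Replicate differences of WT34, CNGCb25 and CNGCb34 correlated at 0.57 to 0.68, but those of WT38 correlated with them at -0.18, -0.52 and -0.17. With the WT38 numbers crossed in the replicate block, calls were 23 for WT34, 31 for WT38, 0 for CNGCb25, 108 for CNGCb34 and 5 for CNGCb34 vs CNGCb25.

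An offset of 10 gave 35 for WT38, 0 for CNGCb25 and 109 for CNGCb34. Median centring gave 3 for CNGCb25 and, for CNGCb34, 1.1e+02 when rounded (89 higher and 16 lower), so 84.8% were higher in CNGCb34 against 71.1% in the reported fit, 97% against 82.5% in WT34 and 87.8% against 69.5% in WT38. Without background correction these shares were 67.6% in WT34 and 52.4% in WT38. The Feature Extraction ratios gave 8 for WT34, 13 for WT38, 15 for CNGCb25, 13 for CNGCb34, 1 for CNGCb34 vs WT34 and 3 for heat by genotype. Their 4 calls in CNGCb34 vs CNGCb25 were 1 higher and 3 lower, so the finding that all calls there were higher did not hold with these ratios. Series table values gave 65 for WT34 and 2 for CNGCb34 vs CNGCb25, and their 1 call in CNGCb25 was higher in place of lower. Leaving out dim probes gave 61 for WT34 and 0 for CNGCb25. The trended robust prior gave 249 for WT34, 0 for CNGCb25 and 293 for CNGCb34. The fold threshold gave 84 for CNGCb34. Turning CNGCb25 replicate 1 or 2 gave 0 for CNGCb25. Removing the GC trend gave 31 for WT38 (29 higher and 2 lower) and 0 for CNGCb25. With the replicate block also fitted it gave 1490 for WT34, 170 for WT38, 0 for CNGCb25, 833 for CNGCb34 and 18 for CNGCb34 vs CNGCb25.

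Leaving out 1 array gave 2 to 32 calls for WT34, 1 to 38 for WT38, 0 for CNGCb25, 2 to 157 for CNGCb34, 1 to 5 for CNGCb34 vs CNGCb25 and 0 for CNGCb34 vs WT34, WT38 vs WT34 and heat by genotype. A lone array was assumed to vary like the other groups. WT34 had 2 calls without WT34 replicate 1, 3 without replicate 2, 6 without either WT38 array and 24 without either CNGCb34 array. WT38 had 1 without WT38 replicate 1, 3 without replicate 2, 20 without either WT34 array, 22 without either CNGCb34 array and 38 without either CNGCb25 array. CNGCb34 had 6 without CNGCb34 replicate 1, 2 without replicate 2, 30 without either WT34 array and 35 without either WT38 array. CNGCb34 vs CNGCb25 had 1 without either CNGCb34 array and 2 without any single WT34 or WT38 array.

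The correlation of WT34 with CNGCb25 moved from 0.50 to -0.081 with ratios from different slides, and to -0.247 or 0.247 with CNGCb25 replicate 1 or 2 turned in sign. That of WT38 with CNGCb25 moved from 0.62 to -0.517 or 0.517 in the same way. Among named probes, Pp_233161 in CNGCb25 went to 0.068 with replicate 1 turned, which follows from arithmetic, since its replicates were both low. In the 15 settings that turned no sign it stayed between -1.25 and -1.45 but lost its call in 12. Of 15 settings, the call was lost in 12 for Pp_155751 and 8 for Pp_92407 (WT34), 11 for Pp_231826 and 9 for Pp_63693 (WT38), and 9 for Pp_75717 and 8 for Pp_92153 (CNGCb34), without a change of sign. With the Feature Extraction ratios Pp_158998 rose by 6.64 in WT34 and 6.23 in CNGCb34 vs CNGCb25, but its adjusted p was 0.0818 and 0.403. In CNGCb34 vs CNGCb25 it lost its call in 8 settings of 17, and Pp_65913 also in 8. The 3 comparisons with 0 calls stayed at 0 in every alternative run except the Feature Extraction ratios. At most 48.9% of gene models were well above background in Cy5 on any array, so the ratios of the others rest on the background correction.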

Other observations

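The sequence classes were added after the files were opened and fixed before any ratio was compared between arrays, whereas the tests of probe lists, shared shifts, exchanged columns, GC content, divisions of the arrays and genotype over both temperatures were chosen after the results had been seen, as was the bound for the heat shock class. Among probes classed by their encoded peptide, the 11 heat shock protein-like probes had a median log2 ratio of -0.01 in WT34 and -0.08 in WT38, with means of 0.52 and 0.57, and 1 probe passed in each. Whether this class rose as a whole in heated wild type was not decided: the larger camera adjusted p was 0.347 over the 4 classes, and 5 of 11 probes were positive in each comparison. The fry adjusted p, which does not set the class against other probes, was 0.104 in WT34 and 0.081 in WT38, and 0.0141 and 0.0137 with slide as a block. The median also depended on the probes included: without dim probes it was 0.27 and 0.22, and at 45, 50 and 65% identity it was -0.08, -0.01 and 0.94 in WT34 and -0.02, -0.03 and 0.95 in WT38. In CNGCb34 vs CNGCb25 the median was 0.48, with 8 of 11 probes positive, a camera adjusted p of 0.0077, which became an adjusted p of 0.284 with an estimated correlation, and a fry adjusted p of 0.0823 (0.0249 with slide as a block). The class median was 0.44 on CNGCb34 replicate 1 and -0.03 on replicate 2, and without replicate 1 the median of CNGCb34 vs CNGCb25 was 0.16, so 1 array carried most of this shift. Across the 4 identity thresholds tried, the preset camera adjusted p in CNGCb34 vs CNGCb25 was 0.283 at 45%, 0.00648 at 50%, 0.0077 at 55% and 0.00091 at 65%, and with an estimated correlation it was 0.682, 0.38, 0.284 and 0.34. In WT34 the preset value was 0.754, 0.403, 0.347 and 0.119. In CNGCb34 vs WT25 the median at 55% was 0.36 (-0.03 without CNGCb34 replicate 1), with a camera adjusted p of 0.125 and a fry adjusted p of 0.0247. At 45, 50 and 65% the preset camera adjusted p was 0.534, 0.0796 and 0.0323. At 65% the median was 1.15, and the camera adjusted p with an estimated correlation was 0.251. The calmodulin-like EF-hand, protein kinase and tubulin classes had medians of 0.09, -0.07 and -0.23 in WT34, with a camera adjusted p of 0.347, 0.636 and 0.347. The fry adjusted p was 0.0952, 0.0952 and 0.147, and with slide as a block 0.0141, 0.224 and 0.0295. In unheated CNGCb25, taken as labelled, the calmodulin-like EF-hand and tubulin medians were 0.19 and -0.22. Their fry adjusted p there was 0.226 each, and 0.0283 each with slide as a block. On CNGCb25 replicates 1 and 2 the calmodulin-like EF-hand medians were 0.03 and 0.235, and the tubulin medians -0.007 and -0.332. These shifts were thus largest on replicate 2, and whether they were particular to heated arrays was not decided. With the series table values the tubulin median was 0.04 and the protein kinase median 0.05. That table holds 0.09 on WT34 replicate 2 wherever the scanner ratio was 0, so this change of sign may come from that value alone. With the Feature Extraction ratios the tubulin median was -0.009.

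The 41 probes raised in WT38 had medians of 1.60 and 1.34 on the WT34 arrays, 1.85 and 1.74 on the CNGCb34 arrays, and 0.22 and 0.13 on the CNGCb25 arrays. In CNGCb34 vs WT34, whose arrays also entered the error terms behind this list, 36 of 41 were positive with a median of 0.22. The fry p was 0.146, so a shift of the list was not established against the spread between arrays. In CNGCb25 vs WT25 the median was 0.20, with 34 of 41 positive and a fry p of 0.0243 (0.0386 with slide as a block), which holds only with both arrays taken as labelled. The list was chosen for rises over the same reference in the same dyes. A dye or reference bias would therefore also make it positive here, and this p does not separate that from a genotype effect. In CNGCb34 vs WT34 the preset camera p was 1.55e-07, but it compares these probes with all others at an assumed low correlation and does not answer for probes that move together.

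Shifts against the reference may come partly from the dyes or the reference RNA. Of the 18 probes lower in WT38, 16 were also below 0 on both unheated CNGCb25 arrays, and the median share of their shift found there was 0.881. On its own, replicate 1 gave 0.93 and replicate 2 gave 0.826. The CNGCb25 arrays entered the error terms behind the called lists, so agreement of its replicates is partly set by the selection. A dye effect follows the colours whichever RNA they hold, so it is consistent with these shares of the probes lower in WT38 even though the direction of CNGCb25 is not settled. For the 52 probes lower in CNGCb34 the median share was 0.946, but for the 7 lower in WT34 it was 0.527, which leaves such an effect open for those. A reference effect needs both arrays to be as labelled, and a genotype effect in CNGCb25 stays open. For the 41 higher probes the median share was 0.081, at 0.12 on replicate 1 and 0.088 on replicate 2. Shares of that size are small in either direction, which argues against such an effect as the whole cause of the rises. The lower calls also depended on the GC content of the probes. Log2 ratios fell with GC content on every array, at a Spearman rho of -0.097 to -0.339. With that trend removed, WT38 had 29 higher and 2 lower calls, against 41 and 18. In CNGCb34 37 were lower in place of 52, and in WT34 5 in place of 7. Whether probe composition caused the lower calls was not tested. Per the labels the arrays hold no dye swap, and no biological explanation of the lower probes was tested.

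The opposed CNGCb25 replicates have no settled cause. Exchanged red and green columns in 1 file are argued against, since on both arrays the Cy3 channel was closer than the Cy5 channel to each of the 3 other Cy3 channels of its slide, by 0.014 in mean Spearman rho on the array with the smaller difference. That test cannot exclude RNA labelled with the opposite dyes, because Cy3 channels could be alike through the dye itself. A GC trend is argued against as the whole cause, because both arrays had been seen to fall with GC content in the same direction. After its removal the correlation was -0.471 in place of -0.402. Removing a trend of the same direction from both was bound to lower it, so that value adds no further support. A slide difference alone is also argued against: of the 35 divisions of the arrays into 4 and 4, the division by slide separated 34 probes by over 0.5 on the log2 scale, and another, with WT38 exchanged between slides, separated 610. The division by slide was still the next highest, and the remaining ones separated at most 4. A slide difference together with crossed WT38 replicates is therefore not argued against. The 41 probes raised in WT38 had medians of 0.22 and 0.13 on the CNGCb25 arrays. On the WT34 and CNGCb34 arrays their medians were 1.34 to 1.85, which argues against an exchange with RNA of a heated sample. Differences between cultures or handling, an exchange with other unheated RNA before hybridisation and opposite labelling stay open.

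Probes that set all 4 CNGCb arrays apart from all 4 WT arrays numbered 4. Of the 35 divisions, 4 separated at least as many, this one included, with 610 as the highest other. The others were the division by slide with 34, the one with WT38 exchanged between slides with 610, and a mixed division with 4. Since slide may lie behind some of these, the rank is not a chance level, and chance cannot be excluded for this pattern. The high value belongs to a division that follows no group and points to a structure among the arrays. Temperature is not balanced here either, since all 4 WT arrays were heated. The contrast of genotype over both temperatures, from CNGCb25 and CNGCb34 against WT34 and WT25, gave 0 calls in limma, with 1837 models at an unadjusted p under 0.05 and 0 calls with slide as a block. WT25 enters this contrast as a log2 ratio of 0, so part of a constant dye effect does not cancel.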
